A study of Mus musculus with 32 samples.

How the data were processed

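The values came as 1 table of probe-set intensity per array, processed by the authors and deposited on a linear scale, with 12488 probe sets in 32 arrays, 399616 values from 0.684 to 58520.1 and none missing. Per the submitters' processing notes the summary method was GCRMA, which corrects background from probe sequence, normalizes between arrays and summarizes probes. Its version, its settings and the arrays normalized together are not given in the sources used here. Per the labels, about 5 µg of total RNA from each individual sample was made into biotinylated cRNA. GCRMA gives log2 values, so the linear table appears to be its output returned to the linear scale. The values were used as deposited, without a further normalization, and taken to log2 after a floor at 1, which 208 values lay below.

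The groups, comparisons, test, filter, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Leaving lactation day 9 replicate 1 out of the stage comparisons it does not enter was added after seeing the data. The groups were taken from the titles because the descriptions of the mammary 8% and 16% arrays name another diet. A design text names only the 8% and 40% diets, each fed for 5 days from lactation day 5, and states liver samples for these animals; liver on 40% fat was not analysed here. How the 16% diet was fed is not stated. The liver and mammary arrays on 8% fat can stem from the same dams, but the labels do not match animals, and the fit treated them as independent. Raw array files were not used here.

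Probe sets were tied to genes by the annotation table of the array, with symbols updated through a RefSeq gene table by Entrez ID, which held 10817 of the 10833 probe sets with a single gene and changed 0 symbols. Another 396 probe sets named several genes and 1193 none; these were tested and counted but never named. A gene was represented by its probe set with the highest mean over all 32 arrays, for 8251 genes. The 66 control probe sets were left out, which left 12422. A probe set was tested where its highest group mean among the groups in the fit reached the median of all values, 18.6 (4.22 in log2). The alternatives tested all probe sets, or used the 75th percentile, 69.5.

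The time course formed a single fit of 20 arrays, the mammary diets a fit of 9 and the tissue comparison a fit of 6, each with limma's linear model and moderated variances. Changes were called at a Benjamini-Hochberg adjusted p under 0.05. Limma p-values rest on the spread between arrays within groups, pooled over the fit. Those of camera, the list test, and Fisher's test compare genes with other genes. Any change over the stages was tested with the moderated F statistic. The share of probe sets whose groups do not overlap was set beside the share that chance gives for groups of that size. The overlap of stage and diet calls was tested with Fisher's test over genes in both fits.

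Lists of 501 genes in 29 groups were written from general knowledge of their function: milk protein, milk fat globule secretion, fatty acid synthesis, cholesterol synthesis, triglyceride synthesis, fatty acid uptake and binding, lipid transcription regulators, beta oxidation, glycolysis, pentose phosphate, lactose synthesis, pyruvate and citric acid cycle, amino acid transport, endoplasmic reticulum folding, ribosomal proteins, cell cycle, gluconeogenesis and ketogenesis, and interferon and inflammation. Markers covered adipocytes, brown adipocytes, luminal and myoepithelial cells, fibroblasts, endothelium, lymphocytes, macrophages, skeletal muscle, hepatocytes and erythrocytes. Of these genes 99, Acaca among them, had no probe set of a single gene. Lists with at least 4 tested genes were tested with camera at its preset inter-gene correlation of 0.01, and again with the correlation estimated from the residuals; Benjamini-Hochberg adjustment ran over the lists of a comparison. Counts of called members are given from the adjustment over all probe sets and from an adjustment over the list alone.

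For lactation day 2 against pregnancy day 17, 40% against 8% fat and liver against mammary gland, the rule named the 5 largest rises and falls among called genes without overlap, up to 4 called and 2 uncalled members per list, and always Srebf1, Fasn, Acaca, Acly, Scd1, Thrsp, Csn2, Wap, Lalba and Lpl. The other comparisons used 3 rises and falls, 2 called members per list and the same fixed genes. List members named beside a list count without being in that rule were chosen after their values were seen.

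The procedure was tested on simulated data with 200 changed probe sets among as many as the real fits held. At a 2-fold change it recovered 87.2% of them for the stage design, 86.6% for the diet design and 83.6% for the tissue design, and at 1.5-fold 51.3%, 51.3% and 49.9%; false calls made up 4.55%, 5.52% and 3.30% of calls. A list of 13 genes shifted by 0.5 was called in 5 of 5 runs of every design at the preset correlation, and with an estimated correlation in 5, 5 and 3 runs. Unchanged lists were called in 0 of 140 tests. Simulated probe sets varied independently, so list calls among correlated genes could not be tested. The 200 changed probe sets were far fewer than the real stage and tissue calls. Real diet calls were below 200, so recovery there can be lower. As a duplicate check, root mean square distances of arrays within groups were 0.200 (smallest), 0.226 (next) and 0.391 (largest). The analysis used R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.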

Results

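The arrays measured RNA levels in mammary gland and liver of FVB mice, in 32 samples, each hybridised to its own array of 12488 probe sets. A time course on chow covered the mammary gland at pregnancy days 12 and 17 and lactation days 1, 2 and 9, with 4 arrays per stage. A diet series at lactation day 10 held 3 mammary arrays each on 8%, 16% and 40% dietary fat and 3 liver arrays on 8% fat. Per the design text, dams on 8% and 40% fat had left chow at lactation day 5. How the 16% diet was fed is not stated. Median intensity per array ran from 16.1 to 21.5. The descriptions of the mammary 8% and 16% arrays read 40% fat, so groups follow the titles, and the 16% diet is named only there. With 3 or 4 arrays per group, the number of arrays limits the precision of every value. Gene values are mean log2 intensities ± SD and changes are log2 differences between group means. A change written as fold is on the linear scale. A group mean below the filter line of 4.22 does not stand above background, so the exact size of a change to or from it was not measured.

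The main question of the time course was how the gland changes as milk secretion begins, tested as lactation day 2 against pregnancy day 17 with 4 arrays each. Several milk genes rose from already high levels: Lalba, which makes the cofactor of lactose synthase, from 10.73 ± 0.44 to 14.75 ± 0.06, Csn1s2b, a casein, from 10.03 ± 0.53 to 13.82 ± 0.14, and Csn2 from 13.90 ± 0.10 to 14.30 ± 0.10. Egf, a growth factor present in milk, rose from 4.35 ± 0.21 to 8.14 ± 0.29 and Slc34a2, a phosphate transporter, from 8.33 ± 0.14 to 12.07 ± 0.31. The steepest falls were in Mt2, a metallothionein, from 10.99 ± 0.22 to 6.31 ± 0.34, and Acot1, an acyl-CoA thioesterase, from 9.65 ± 0.27 to 5.42 ± 0.63. Phlda1 (-3.34), Plscr2 (-3.19) and Kit (6.36 ± 0.53 to 3.27 ± 0.05, the latter below the filter line) fell too. Of 7189 probe sets tested, 1830 were higher and 1759 lower at lactation day 2 by limma with Benjamini-Hochberg adjustment, 3589 in all. Of these, 240 rose and 504 fell by at least 2-fold. The 4 arrays of each stage did not overlap for 3614 probe sets (50.3%, where chance gives 2.86%). Setting the ribosomal protein medians of the arrays equal shifted every change upward by 0.519. It gave 5086 higher and 578 lower of the 7721 probe sets that then passed the filter.

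Lipid synthesis genes rose with secretion. In the fatty acid synthesis list 11 of 13 genes were higher and 1 lower over all probe sets, and the same 11 and 1 when adjusted over the list alone (median change 0.82, camera adjusted p = 2.27e-05, adjusted p = 0.191 with an estimated correlation). Elovl5, a fatty acid elongase, rose by 2.67 (9.48 ± 0.26 to 12.15 ± 0.13), Slc25a1, the citrate carrier, by 2.65 and Scd2, a desaturase, by 2.24. Acly, which splits citrate to acetyl-CoA, rose by 1.44 (12.27 ± 0.18 to 13.71 ± 0.16), Fads1 by 1.25, Thrsp by 0.87, Mid1ip1 by 0.82, Elovl1 by 0.81, Fasn by 0.71 (12.75 ± 0.19 to 13.46 ± 0.11) and Me1 by 0.61. Scd1 rose by 0.77 on its brightest probe set, while another of its probe sets fell by 1.43 (adjusted p = 0.0207). Dbi, an acyl-CoA binding protein, fell by 0.69, and Elovl6 differed by 0.44 (adjusted p = 0.125). Among lipid transcription regulators Srebf1, which drives sterol and fatty acid genes, rose by 1.21 (9.43 ± 0.17 to 10.64 ± 0.43) and Mlx by 0.59, and Nr1h3 fell by 0.79. Akt1, a kinase held in the same list, rose 2.82-fold on the linear scale. In this list 4 of 11 were higher and 1 lower, or 4 and 4 over the list alone, and the list was not called (median 0.18, adjusted p = 0.249). In cholesterol synthesis 12 of 16 genes were higher and 0 lower, alone also 12 and 0 (median 0.93, adjusted p = 2.27e-05, adjusted p = 0.191 with an estimated correlation). The largest rises were in Dhcr7 (2.35, 5.19 ± 0.65 to 7.54 ± 0.46), Fdps (2.28), Nsdhl (2.25) and Sqle (1.68).

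Fatty acid breakdown fell at the same stage. Of 23 beta oxidation genes 16 were lower and 0 higher, alone 16 lower and 2 higher (median -0.74, camera adjusted p = 1.70e-05, adjusted p = 0.191 with an estimated correlation). Cpt1a, which lets fatty acids enter mitochondria, fell by 1.94 (6.03 ± 0.56 to 4.09 ± 0.09, below the filter line, so the exact size was not measured), Acaa2 by 2.83-fold, Eci2 by 1.41 and Cpt2 by 1.37. Adipocyte (median -0.71, adjusted p = 0.00408), fibroblast (median -0.96) and macrophage markers (median -0.58) were lower in the same comparison, so the fall was not separated from a change in cell types. These 3 calls were lost with an estimated correlation (adjusted p = 0.346 each), and the macrophage call also without lactation day 2 replicate 4 or pregnancy day 17 replicate 1. Triglyceride synthesis genes moved both ways, with Lpin1 (1.36), Gpd1 (1.16) and Agpat1 (0.85) higher and Agpat3 (-0.74) lower. In this list 3 of 11 were higher and 2 lower, alone 3 and 2 (median 0.06, adjusted p = 0.707). In fatty acid uptake and binding Slc27a4 rose by 0.97 and Lrp1 fell by 0.97, 3 of 12 were higher and 3 lower, alone 3 and 3 (median 0.11, adjusted p = 0.615), and Lpl stood at 12.61 ± 0.11 against 12.34 ± 0.14 (adjusted p = 0.105). The uptake list shares 4 of its genes with other lists.

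In the milk protein list 8 of 13 genes were higher and 0 lower, alone 8 and 0 (median 0.41, mean 1.05, camera adjusted p = 0.00131, adjusted p = 0.346 with an estimated correlation). Lcn2 rose by 0.73. Wap (15.75 against 15.72), Glycam1 (change 0.18) and Csn1s1 (change 0.04) did not pass. Wap lay near the top of the intensity scale at both stages, so its flat values cannot show whether it rose. Lalba, Muc1 and Lcn2 of this list are also members of other lists. Milk fat globule genes gave 6 higher and 2 lower of 10, alone 6 and 2 (median 0.68, adjusted p = 0.0319, adjusted p = 0.346 with an estimated correlation). This call was lost without the filter (adjusted p = 0.240) and with ribosomal medians set equal (adjusted p = 0.292). Muc1, a mucin of the globule membrane, rose by 2.66, Cidea, a lipid droplet protein, by 2.63 (10.21 ± 0.22 to 12.84 ± 0.06), Xdh by 1.69 and Btn1a1 by 1.12, and Anxa1 fell by 2.33 and Plin2 by 0.39. Cidea, Muc1, Cd36 and Fabp3, 4 of these 10 genes, sit in other lists too. In lactose synthesis Slc2a1 rose by 1.58 and Galt by 0.56 and Hk1 fell by 0.73. In this list 3 of 9 were higher and 2 lower, alone 3 and 2, with a median of -0.03 (0.49 with ribosomal medians set equal, 0.01 after quantile normalization), a mean of 0.56 and the test upward (adjusted p = 0.479). Lalba, Slc2a1 and Hk1 of this list are held by others.

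Carbon supply genes changed in part. Aldoc, a glycolytic aldolase, rose by 2.59 (9.20 ± 0.30 to 11.79 ± 0.12), Pkm by 0.79 and Ldha by 0.76. In this list 6 of 16 were higher and 2 lower, alone 6 and 2 (median 0.24, camera adjusted p = 0.0319, adjusted p = 0.346 with an estimated correlation). That call was lost without the filter (adjusted p = 0.266), with ribosomal medians set equal (adjusted p = 0.168) and with the mean of all probe sets of a gene (adjusted p = 0.0539). Cs (1.17) and Pcx (1.07) rose and Pdk4 (-1.65), which blocks pyruvate oxidation, and Idh1 (-0.89) fell. In the pyruvate and citric acid cycle 5 of 23 were higher and 7 lower, alone 5 and 7, with a median of -0.06 (0.46 with ribosomal medians set equal, 0.06 after quantile normalization, adjusted p = 0.878). Pgd (0.81) and Tkt (0.62) rose and Pgls (-0.56) and Taldo1 (-0.39) fell in the pentose phosphate pathway, 2 of 6 each way, alone 2 and 2 (median 0.07, adjusted p = 0.830). Gluconeogenesis and ketogenesis had 3 genes, 1 higher and 1 lower, alone 1 and 1, too few to test. Amino acid carriers Slc38a2 (1.60), Slc7a7 (1.17) and Slc1a4 (1.04) rose and Slc1a5 (-1.28) fell. In this list 4 of 7 were higher and 3 lower, alone 4 and 3 (median 0.65, adjusted p = 0.507).

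Protein and growth genes split. Cell cycle genes gave 13 higher and 0 lower of 21, alone 13 and 0 (median 1.23, camera adjusted p = 3.41e-05, adjusted p = 0.346 with an estimated correlation, adjusted p = 0.0571 with ribosomal medians set equal). Rrm2, which makes deoxynucleotides, rose by 3.56, Mcm5, a replication helicase subunit, by 2.90 (5.96 ± 0.32 to 8.86 ± 0.43), Mki67 by 2.22 (7.41 ± 0.51 to 9.62 ± 0.35) and Mcm4 by 1.97, from below the filter line. In endoplasmic reticulum protein folding Dnajb9 (1.41), Ssr1 (1.09), Pdia6 (0.69) and Sec61a1 (0.55) rose. In this list 5 of 16 were higher and 0 lower, alone 5 and 0 (median 0.18, adjusted p = 0.231, adjusted p = 0.0255 with the 75th percentile filter). The Pdia6 call was lost without pregnancy day 17 replicate 4 (adjusted p = 0.0614). Ribosomal protein genes gave 10 lower and 0 higher of 11, alone 10 and 0, among them Rps7 (-0.68), Rps19 (-0.56) and Rps3 (-0.51), with a median of -0.48 that turned to 0.10 when ribosomal medians were set equal (adjusted p = 0.00109, adjusted p = 0.191 with an estimated correlation, adjusted p = 0.175 under that scaling). That scaling evens out this very list by construction, so the turn does not test whether these genes fell. In interferon and inflammation Hp (-1.69), Gbp2 (-1.58) and Saa3 (-1.02, lost without 3 of the 8 arrays, adjusted p up to 0.0903) fell. In this list 1 of 14 was higher and 3 lower, alone 1 and 3, with a median of -0.10 (0.41 with ribosomal medians set equal, adjusted p = 0.507).

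Markers of stromal and fat cells were lower at lactation day 2. Fibroblast and matrix genes gave 11 lower and 0 higher of 16, alone 13 and 0 (median -0.96, camera adjusted p = 0.00110, adjusted p = 0.346 with an estimated correlation): Col6a3 fell by 1.62 (7.78 ± 0.17 to 6.16 ± 0.35), Col5a2 by 1.28, Fbln2 by 2.29-fold and Col1a2 by 1.67, although another Col1a2 probe set rose by 0.54. Col1a1 (-0.49) and Sparc (-0.03) did not pass. Adipocyte genes gave 9 lower and 0 higher of 15, alone 10 and 0 (median -0.71, adjusted p = 0.00408, adjusted p = 0.346 with an estimated correlation, adjusted p = 0.0663 with the 75th percentile filter). Sncg (-2.44), Lep (-1.70), Lipe (-1.32) and Retn (-1.12) fell. Fabp4, Slc2a4, Pparg and Lpl are shared with other lists. Macrophage genes gave 7 lower and 0 higher of 11, alone 7 and 0 (median -0.58, adjusted p = 0.0352, adjusted p = 0.346 with an estimated correlation). C1qb (-1.27), C1qa (-1.15), C1qc (-0.96) and Tyrobp (-0.86) fell. The macrophage call was lost without lactation day 2 replicate 4 (adjusted p = 0.0528), without pregnancy day 17 replicate 1 (adjusted p = 0.0576), with the 75th percentile filter (adjusted p = 0.0795) and with the mean of all probe sets of a gene (adjusted p = 0.117). Endothelial Pecam1 (0.69) and Flt1 (0.27, lost without 7 of the 8 arrays, adjusted p up to 0.135) rose and Cav1 fell (9.18 to 8.18). In this list 2 of 10 were higher and 1 lower, alone 1 and 1 (median 0.00, adjusted p = 0.836). The 2 erythrocyte genes tested gave 0 calls, alone 0 (median -0.69, Hba-a1 -0.96 with adjusted p = 0.157), too few for a test.

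Epithelial markers also fell in part. Luminal Cldn3 (-2.70), Cldn4 (-2.49), Krt7 (-2.10) and Epcam (-1.30), which encode junction, keratin and adhesion proteins, fell, Cldn4 and Krt7 to below the filter line. In this list 8 of 13 were lower and 1 higher, alone 8 and 1, with a median of -0.48 that turned to 0.07 when ribosomal medians were set equal (camera adjusted p = 0.00241, adjusted p = 0.191 with an estimated correlation). Under the ribosomal scaling camera still called the list downward (adjusted p = 0.00349). Myoepithelial Mylk (-1.36), Tagln (-1.04) and Acta2 (-0.92) fell, with 4 of 7 lower and 0 higher, alone 5 and 0, and a median of -0.50 (adjusted p = 0.0550). That list passed with ribosomal medians set equal (median 0.02, test downward, adjusted p = 0.0376), with only the compared groups in the fit (adjusted p = 0.0402) and without lactation day 2 replicate 1 (adjusted p = 0.0308). Brown adipocyte genes gave 4 higher and 0 lower of 5, alone 4 and 0 (median 0.34, adjusted p = 0.0319, adjusted p = 0.224 with an estimated correlation): Cidea, also a milk fat globule gene, Ucp1 (1.39, adjusted p = 0.0398), Elovl3 (0.34) and Cox7a1 (0.30). Of these, Ucp1 was lost without 5 of the 8 arrays (adjusted p up to 0.170) and Elovl3 without 4 (adjusted p up to 0.0942). The brown call was lost without the filter (adjusted p = 0.0813) and with ribosomal medians set equal (adjusted p = 0.0914), and the 75th percentile filter left too few genes for a test.

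Marker genes of other tissues rose at low intensity at lactation day 2. Hepatocyte genes gave 6 higher and 0 lower of 7, alone 7 and 0 (median 0.27, camera adjusted p = 0.0246, adjusted p = 0.346 with an estimated correlation). Cyp2e1 rose by 0.56, Apoa2 by 0.43 (3.75 to 4.17), Fgg by 0.30 and F2 by 0.27, and 5 of the 6 lay below the 75th percentile of intensity. The Cyp2e1 call was lost without 5 of the 8 arrays (adjusted p up to 0.147). Quantile normalization, the 75th percentile filter and fitting only the compared groups each left this list too few genes for a test. Lymphocyte Ms4a1 (0.75), Cd79a (0.58), Cd3d (0.55) and Cd3g (0.43) rose. In this list 5 of 9 were higher and 0 lower, alone 5 and 1 (median 0.42, adjusted p = 0.0836), and all 5 lay below the 75th percentile. Skeletal muscle Tnnt3 (0.34) and Tnni2 (0.27) rose, 2 of 6 with 0 lower, alone 2 and 0 (median 0.19, adjusted p = 0.266), and both lay below it. Tnni2 was lost without lactation day 2 replicate 3 or pregnancy day 17 replicate 1 (adjusted p = 0.0631 and 0.0752).

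**Figure D1:**
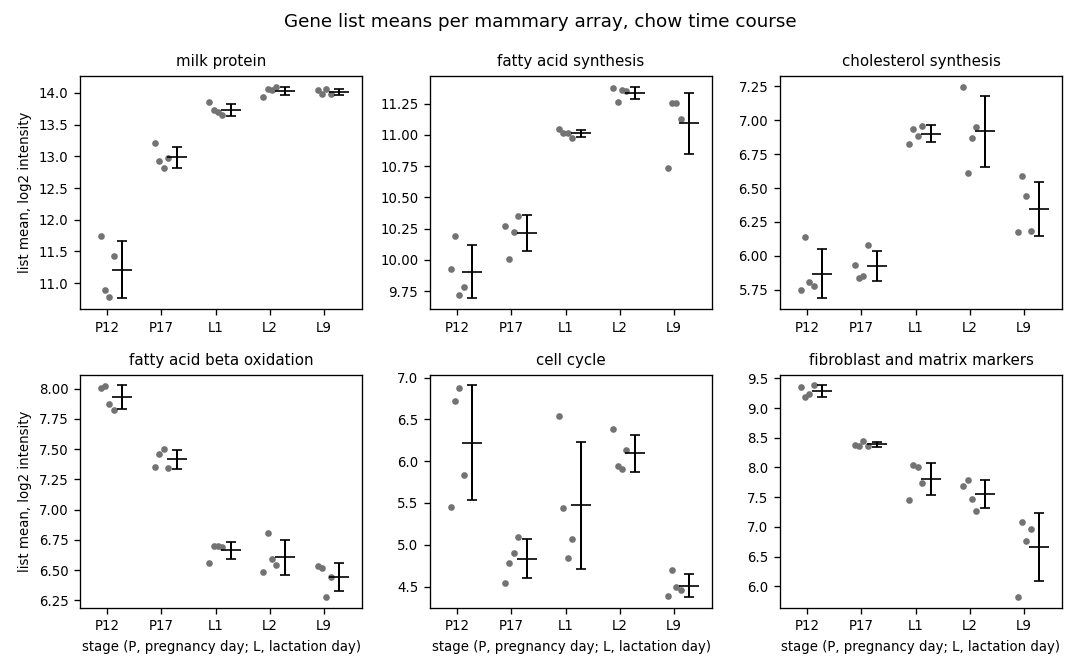
Mean log2 intensity of 6 gene lists (vertical axis) in each of the 20 chow mammary arrays by stage (horizontal axis, with P for pregnancy day and L for lactation day), where points are arrays, and the dash with its bar is the mean ± SD of 4 arrays. Group means ran from 9.90 at pregnancy day 12 to 11.34 at lactation day 2 for fatty acid synthesis, from 7.93 to 6.61 for beta oxidation and from 9.29 to 7.55 for fibroblast and matrix genes.

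Late pregnancy was compared as day 17 against day 12, with 4 arrays each. The day 17 arrays are those used above. Saa2, an acute-phase protein, rose from 3.92 ± 0.59 to 10.58 ± 0.39, Csn1s2b by 5.58, Xist by 4.08, Cel, a milk lipase, by 3.40, Cidea by 2.83, Saa3 by 2.77, Lalba by 2.22, Fabp3 by 1.91 and Wap by 1.48 (14.24 ± 0.58 to 15.72 ± 0.04). Slc2a1 (1.25), Ssr1 (0.96), Xbp1 (0.84), Lpl (0.55) and Csn2 (0.42) rose less. Cmbl (-2.89), Ifi27l2a (-2.85), Nnmt (-2.77), Pck1 (-2.65), Mcm4 (-2.44), Rrm2 (-2.40), Alas2 (-2.23), Cyp2e1 (-2.00), Col6a3 (-1.86), Col6a2 (-1.80), Cpt1a (-1.79), Pparg (-1.71), Decr1 (-1.23) and Srebf1 (-0.71) fell. Saa2 at day 12 and Nnmt, Mcm4 and Alas2 at day 17 lay below the filter line. The lipid synthesis genes Fasn (0.30), Scd1 (0.17), Acly (0.06) and Thrsp (-0.03) did not pass. Camera did not call the fatty acid synthesis list (median 0.17, adjusted p = 0.0692). It passed with the 75th percentile filter (adjusted p = 0.0463), with only the compared groups (adjusted p = 0.0297) and with the mean of all probe sets (adjusted p = 0.0323). Leaving out pregnancy day 12 replicate 2 (adjusted p = 0.0131) or day 17 replicate 2 (adjusted p = 0.0279) also gave a call. Of 7189 probe sets 1322 were higher and 1923 lower by limma with Benjamini-Hochberg adjustment, 223 and 544 of them by at least 2-fold. Setting ribosomal medians equal turned that balance, with 2219 higher and 1629 lower.

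From pregnancy day 12 to 17 camera called 7 lists, none of them with an estimated correlation. All 13 milk protein genes were higher, alone 13 (median 1.46, adjusted p = 1.56e-11, adjusted p = 0.121 with an estimated correlation), and 9 of 10 milk fat globule genes, alone 9 (median 1.51, adjusted p = 4.79e-07, adjusted p = 0.121 with an estimated correlation). Endoplasmic reticulum genes gave 6 higher of 16, alone 6 (median 0.35, 0.21 without pregnancy day 17 replicate 3, adjusted p = 0.0177, adjusted p = 0.596 with an estimated correlation, adjusted p = 0.0619 without the filter). Lactose synthesis gave 6 higher and 1 lower of 9, alone 6 and 1 (median 0.48, adjusted p = 0.0405, adjusted p = 0.255 with an estimated correlation). It was lost without pregnancy day 12 replicate 2 (adjusted p = 0.0583), without pregnancy day 17 replicate 1 (adjusted p = 0.0557), with ribosomal medians set equal (adjusted p = 0.0660) and without the filter (adjusted p = 0.178). Cell cycle genes gave 16 lower and 0 higher of 21, alone 17 and 1 (median -1.62, adjusted p = 5.53e-04, adjusted p = 0.596 with an estimated correlation), beta oxidation 13 lower of 23, alone 15 (median -0.45, adjusted p = 0.00171, adjusted p = 0.474 with an estimated correlation), and fibroblast and matrix genes 11 lower of 16, alone 11 (median -1.03, adjusted p = 0.00552, adjusted p = 0.596 with an estimated correlation). Adipocyte markers were also lower but not called (median -0.76, camera adjusted p = 0.0692). Among other settings, they passed without the filter (adjusted p = 0.00831), with quantile normalization (adjusted p = 0.0313) and with ribosomal medians set equal (adjusted p = 0.0296). The beta oxidation fall was therefore not separated from a change in cell types. Setting ribosomal medians equal shifted every change upward by 0.0803.

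Lactation day 1 against pregnancy day 17 asked what differs between late pregnancy and the first day of lactation, again with 4 arrays per group and the same day 17 arrays. Atp2b2, a calcium pump of milk secretion, rose by 3.61 (4.46 ± 0.19 to 8.07 ± 0.39), Slc34a2 by 3.53, Csn1s2b by 3.41, Cidea by 2.74, Lalba by 2.64, Aldoc by 2.42 and Muc1 by 2.29. Lipid synthesis genes rose between these stages: Elovl5 by 2.31, Scd2 by 2.11, Fdps by 1.88, Nsdhl by 1.73, Acly by 1.15, Srebf1 by 1.04, Thrsp by 0.80 and Scd1 by 0.71, with Lpl up by 0.66 and Fasn at 0.43 (adjusted p = 0.0504). Without pregnancy day 17 replicate 4 Fasn passed (adjusted p = 0.0472), and without replicate 1 Scd1 was lost (adjusted p = 0.0515). Ssr1 rose by 1.08 and Pdia6 by 1.04. Mt2 (-4.92), Acot1 (-4.61), Plscr2 (-3.29), Cldn3 (-2.62), Cldn4 (-2.54), Cpt1a (-2.03) and Lep (-1.78) fell, Cldn4 and Cpt1a to below the filter line. Csn2 (0.16) and Wap (-0.10, 0.25 with ribosomal medians set equal) did not pass. Wap lay near the top of the intensity scale, where a rise might not show. By limma with Benjamini-Hochberg adjustment 670 of 7189 probe sets were higher and 1004 lower, 172 and 225 by at least 2-fold. Ribosomal scaling shifted every change upward by 0.345 and gave 4268 higher and 413 lower.

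At lactation day 1 camera called 14 lists, and each was lost with an estimated correlation. Cholesterol synthesis gave 13 higher of 16, alone 14 (median 0.99, adjusted p = 2.51e-09, adjusted p = 0.0966 with an estimated correlation), fatty acid synthesis 8 higher and 1 lower of 13, alone 9 and 1 (median 0.74, adjusted p = 3.90e-05, adjusted p = 0.139 with an estimated correlation), and endoplasmic reticulum folding 8 higher of 16, alone 8 (median 0.48, adjusted p = 3.28e-04, adjusted p = 0.158 with an estimated correlation). Milk protein gave 3 higher of 13, alone 3 (median 0.19, 0.31 without pregnancy day 17 replicate 1, adjusted p = 0.00536, adjusted p = 0.416 with an estimated correlation), milk fat globule 5 higher and 2 lower of 10, alone 6 and 2 (median 0.69, adjusted p = 0.00790, adjusted p = 0.274 with an estimated correlation, adjusted p = 0.149 with ribosomal medians set equal), and brown adipocyte 1 of 5, alone 1 (median 0.22, adjusted p = 0.0122, adjusted p = 0.139 with an estimated correlation). Cell cycle gave 7 higher of 21, alone 7 (median 0.55, adjusted p = 0.00293, adjusted p = 0.489 with an estimated correlation, adjusted p = 0.304 with ribosomal medians set equal). Without lactation day 1 replicate 1 the median was 0.09 and the call was lost (adjusted p = 0.169).

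Lower at lactation day 1 by camera were beta oxidation, 15 of 23, alone 15 with 1 higher (median -0.71, adjusted p = 7.55e-08, adjusted p = 0.0966 with an estimated correlation), luminal markers, 7 of 13, alone 7 (median -0.47, adjusted p = 4.71e-04, adjusted p = 0.116 with an estimated correlation), and fibroblast and matrix genes, 4 of 16, alone 6 (median -0.60, adjusted p = 0.00293, adjusted p = 0.416 with an estimated correlation). Ribosomal proteins gave 7 lower of 11, alone 9, with a median of -0.34 that turned to 0.01 when ribosomal medians were set equal (adjusted p = 0.00122, adjusted p = 0.0966 with an estimated correlation, adjusted p = 0.0782 under that scaling). The scaling fixes this list by construction, so the turn does not test its fall. Myoepithelial markers gave 4 lower of 7, alone 4 (median -0.70, adjusted p = 0.0119, adjusted p = 0.274 with an estimated correlation), and macrophage markers 4 of 11, alone 5 (median -0.35, adjusted p = 0.0134, adjusted p = 0.297 with an estimated correlation). Adipocyte markers gave 3 lower and 1 higher of 15, alone 5 and 1 (median -0.40, adjusted p = 0.0490, adjusted p = 0.489 with an estimated correlation). The adipocyte call was lost without lactation day 1 replicate 1 (median -0.24, adjusted p = 0.301) and without pregnancy day 17 replicates 1, 2 or 3 (adjusted p = 0.0681, 0.0593 and 0.0693), with the 75th percentile filter (adjusted p = 0.192), with only the compared groups in the fit (adjusted p = 0.0766) and with an offset of 16 (adjusted p = 0.0553). The brown adipocyte list had too few genes for a test with the 75th percentile filter.

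Lactation day 2 against day 1, which shares both groups with the comparisons above, asked what follows in the next day. Cell cycle Birc5 rose by 1.51 and Tk1 by 0.99, and lipid genes Dhcr7 by 1.14, Slc27a4 by 0.76, Elovl6 by 0.75 and Mid1ip1 by 0.63. Atp13a2 (1.45), Jup (1.38), Ace (1.30), Slc7a5 (0.84), Akt1 (0.69), Pkm (0.68) and Cs (0.62) rose. Cmip (-1.92), Xist (-1.80), Sncg (-1.68), Ighm (-1.43, with another probe set 0.64 higher), Jchain (-1.32), Pck1 (-1.14), Dcn (-0.85), Epcam (-0.84), Adipoq (-0.76) and Pdia4 (-0.74) fell. Ace at day 1 and Cmip at day 2 lay below the filter line. Lalba stood at 14.75 ± 0.06 against 13.38 ± 0.18 (adjusted p = 0.0547), and Acly (0.29), Fasn (0.28), Srebf1 (0.18) and Scd1 (0.06) did not pass. By limma with Benjamini-Hochberg adjustment 439 of 7189 probe sets were higher and 588 lower, 23 and 83 by at least 2-fold. Without the filter that balance turned, with 643 higher and 514 lower. Ribosomal scaling shifted every change upward by 0.174 and gave 2497 higher and 352 lower. The total of 1027 was 1332 without lactation day 1 replicate 1 and fell to 561, 523 and 595 without its replicates 2, 3 and 4, and to 642 and 600 without lactation day 2 replicates 3 and 4. Leaving out 1 of the 8 arrays ended the calls of Elovl6 and Adipoq (6 arrays each), Birc5 and Ace (5 each), Pck1 and Ighm (4 each), Mid1ip1 and Jchain (3 each) and Dhcr7 and Tk1 (2 each), with adjusted p up to 0.112.

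Camera called 2 lists between lactation days 1 and 2. Cell cycle gave 3 higher of 21, alone 3 (median 0.75, adjusted p = 0.00722, adjusted p = 0.880 with an estimated correlation). It was lost without lactation day 1 replicate 3, with a median of 0.45 (adjusted p = 0.0817), without the filter (adjusted p = 0.0984) and with ribosomal medians set equal (adjusted p = 0.0735). Fatty acid synthesis gave 2 higher of 13, alone 3 (median 0.28, adjusted p = 0.0242, adjusted p = 0.880 with an estimated correlation). This list was lost without the filter (adjusted p = 0.117), with ribosomal medians set equal (adjusted p = 0.0735) and with the mean of all probe sets of a gene (adjusted p = 0.170). Without lactation day 1 replicate 1 camera called adipocyte (adjusted p = 0.00269), fibroblast (adjusted p = 0.0430) and endoplasmic reticulum genes (adjusted p = 0.0158) lower and milk protein genes higher (adjusted p = 0.0430).

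Lactation day 9 against day 2 compared established with early lactation, 4 arrays each. Egf rose further, from 8.14 ± 0.29 to 10.78 ± 0.14, with the immunoglobulin genes Ighm (2.56) and Jchain (1.76), Slc39a8, a metal transporter (2.54), Orm1 (2.22), Alas2 (1.45), Slc27a3 (1.24) and Cidea (0.70). Alas2 and Slc27a3 lay below the filter line at day 2. Saa2 (-3.97), Fam3c (-3.90), Mcm5 (-3.83, 8.86 ± 0.43 to 5.03 ± 0.74), Rrm2 (-3.54), Krt19 (-2.71), Dhcr7 (-2.31), Lum (-1.91), Pkm (-1.65), Nsdhl (-1.57), Gpd1 (-1.47), Sparc (-1.45), Tkt (-1.24), Pgd (-1.24), Scd2 (-1.24), Pdia3 (-1.16), Ldha (-0.93) and Acly (-0.36, adjusted p = 0.0430) fell. Fasn (-0.22), Csn2 (0.01), Wap (0.00), Srebf1 (-0.06) and Thrsp (0.39) did not pass, nor did Scd1 (-0.40), whose dimmest probe set rose by 2.35. Wap again lay near the top of the intensity scale, where a rise might not show. Without lactation day 9 replicate 1 Fasn was at -0.05 and Scd1 at -0.17, Srebf1 turned to 0.04, Csn2 to -0.05 and Wap to -0.01, and Thrsp passed (0.53, adjusted p = 0.0353). Acly was lost without 6 of the 8 arrays (adjusted p up to 0.147) and Alas2 without 5 (adjusted p up to 0.0882). By limma with Benjamini-Hochberg adjustment 634 of 7189 probe sets were higher and 1163 lower, 143 and 302 by at least 2-fold. Quantile normalization gave 937 and 925.

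Camera called 7 lists at lactation day 9, each with adjusted p = 0.458 with an estimated correlation. Lower were cell cycle, 16 of 21, alone 16 (median -1.73, adjusted p = 2.61e-07), fibroblast and matrix, 11 of 16, alone 13 (median -0.98, adjusted p = 1.09e-04), pentose phosphate, 3 of 6, alone 5 (median -0.84, adjusted p = 0.00538), endoplasmic reticulum folding, 9 of 16, alone 9 (median -0.61, adjusted p = 0.0203), cholesterol synthesis, 7 of 16, alone 10 (median -0.59, adjusted p = 0.0204), and glycolysis, 8 of 16 with 1 higher, alone 8 and 1 (median -0.42, adjusted p = 0.0319). Hepatocyte markers gave 2 higher of 7, alone 2 (median 0.21, adjusted p = 0.0278). Low intensities rose here too. Leaving out lactation day 9 replicate 1, the lowest of its stage in stromal list means, gave 10 lower fibroblast genes (median -0.69, adjusted p = 1.83e-04) and 15 lower cell cycle genes (adjusted p = 4.97e-07). Glycolysis (adjusted p = 0.0536) and hepatocyte markers (adjusted p = 0.0608) were lost. Without replicate 4 cholesterol synthesis (adjusted p = 0.0534), glycolysis (adjusted p = 0.0534) and hepatocyte markers (adjusted p = 0.0805) were lost, and without lactation day 2 replicate 1 cholesterol synthesis was lost (adjusted p = 0.0816). With the 75th percentile filter pentose phosphate (adjusted p = 0.0951), endoplasmic reticulum folding (adjusted p = 0.113), cholesterol synthesis (adjusted p = 0.107) and glycolysis (adjusted p = 0.113) were lost, and hepatocyte markers had too few genes for a test. Quantile normalization ended the calls of cholesterol synthesis (adjusted p = 0.0502) and glycolysis (adjusted p = 0.242) and left too few hepatocyte markers, and with only the compared groups in the fit glycolysis was lost (adjusted p = 0.0751). The 2 erythrocyte genes gave 1 higher with all arrays and 2 higher, with a median of 1.97, without lactation day 9 replicate 1.

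A test for any change over the 5 stages called 6293 of 7189 probe sets (87.5%) by limma with Benjamini-Hochberg adjustment, where 6342 passed unadjusted. Leaving out each array in turn gave 6111 to 6357.

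The diet question was whether dietary fat lowers lipid synthesis genes in the lactating gland, tested as mammary 40% against 8% fat with 3 arrays each. Scd1, the desaturase that makes oleate, fell from 14.54 ± 0.01 to 13.26 ± 0.10 (adjusted p = 0.00118), and its second probe set fell by 0.82 (adjusted p = 0.0178). Slc25a1, the mitochondrial citrate carrier, fell from 12.41 ± 0.07 to 11.56 ± 0.10 (adjusted p = 0.0231). Slc4a2, an anion exchanger, rose from 5.12 ± 0.07 to 5.96 ± 0.09 (adjusted p = 0.0231), AU020206 by 0.85 (adjusted p = 0.0456) and Col9a1 by 0.89 (adjusted p = 0.0337). These 6 probe sets, 3 higher and 3 lower of 6483, were all that limma with Benjamini-Hochberg adjustment called. Unadjusted, 538 passed, and the 3 arrays of each group did not overlap for 851 (13.1%, where chance gives 10%). The total was 4 without 40% replicate 1, 1 without 40% replicate 2 or 8% replicate 3, 2 without 40% replicate 3 or 8% replicate 2 and 3 without 8% replicate 1. It was 1 with only the compared groups in the fit. Slc4a2 and AU020206 were lost without each of the 6 arrays and Slc25a1 and Col9a1 without 5 (adjusted p up to 0.188).

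The fatty acid synthesis list fell as a group on 40% fat. All 13 genes were below 0, 2 of them called over all probe sets and 10 when adjusted over the list alone (median -0.44, camera adjusted p = 1.16e-16, adjusted p = 0.00232 with an estimated correlation). Beside Scd1 and Slc25a1, Elovl6 differed by -0.90, Scd2 by -0.80, Me1 by -0.65 (adjusted p = 0.0796), Mid1ip1 by -0.56, Elovl5 by -0.44, Fasn by -0.40 (13.13 ± 0.06 against 13.53 ± 0.09, adjusted p = 0.190), Thrsp by -0.38 and Acly by -0.21, and none passed over all probe sets. Srebf1 stood at 9.88 ± 0.29 against 10.60 ± 0.23 (adjusted p = 0.322). The mean of the list was 11.49 ± 0.08 on 8%, 11.40 ± 0.02 on 16% and 10.96 ± 0.02 on 40% fat.

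Of the other lists camera called 5 on 40% against 8% fat, none with an estimated correlation. Cholesterol synthesis had 0 genes called of 16 over all probe sets and 4 lower alone (median -0.23, adjusted p = 8.18e-05, adjusted p = 0.273 with an estimated correlation). Its median was -0.15 without 40% replicate 1. Nsdhl was at -0.77, Dhcr7 at -0.68, Fdps at -0.62, Mvd at -0.52 and Sqle at -0.49. The pentose phosphate pathway had 0 of 5 and 3 lower alone (median -0.32, adjusted p = 0.00633, adjusted p = 0.317 with an estimated correlation). Tkt was at -0.41 and Taldo1 at -0.32. Without 40% replicate 3 the median was -0.20. Fibroblast and matrix genes had 0 of 15 and 5 higher alone. The median was -0.01 (0.03 with ribosomal medians set equal), the mean 0.33 and the test upward (adjusted p = 0.0136, adjusted p = 0.377 with an estimated correlation). Col6a3 was at 1.16, Col1a1 at 0.96, Sparc at 0.88, Col1a2 at 0.83 and Col3a1 at 0.69. Leaving out any single array turned the median upward (0.03 to 0.16). The call was lost without 40% replicate 3 (median 0.16, adjusted p = 0.0511) and without 8% replicate 3 (median 0.06, adjusted p = 0.09999). Myoepithelial genes had 0 of 6, alone 0 (median -0.21, Acta2 -0.47, adjusted p = 0.0328, adjusted p = 0.597 with an estimated correlation). It was lost without 40% replicates 1 (adjusted p = 0.112) or 3 (adjusted p = 0.0511) and 8% replicates 1 (adjusted p = 0.142) or 2 (adjusted p = 0.0954) and with the 75th percentile filter (adjusted p = 0.0709). The pyruvate and citric acid cycle had 0 of 22, alone 0 (median -0.10, Cs -0.45, Pcx -0.37, adjusted p = 0.0478, adjusted p = 0.555 with an estimated correlation). It was lost without 40% replicates 2 (adjusted p = 0.0663) or 3 (median -0.04, adjusted p = 0.255) and 8% replicates 1 (adjusted p = 0.0727) or 2 (adjusted p = 0.147). It was also lost with the 75th percentile filter (adjusted p = 0.140), with quantile normalization (adjusted p = 0.235), with ribosomal medians set equal (adjusted p = 0.0837) and with the replicate number as a block (adjusted p = 0.0564).

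Milk genes showed no call by camera on 40% against 8% fat. Milk protein had 0 of 13, alone 0, with a median of -0.02 and a mean of 0.03 (adjusted p = 0.879). Csn2 was at 0.03, Wap at -0.05 and Lalba at 0.44. Milk fat globule had 0 of 10, alone 0, with a median of -0.01 and a mean of 0.02 (adjusted p = 0.930, Cidea 0.02). Triglyceride synthesis (0 of 11, alone 0, median -0.04, adjusted p = 0.879), uptake (0 of 11, alone 1 higher, median 0.02, adjusted p = 0.879, Lpl -0.21), beta oxidation (0 of 22, alone 0, median -0.04, adjusted p = 0.502), glycolysis (0 of 16, alone 0, median -0.10, adjusted p = 0.155) and endoplasmic reticulum folding (0 of 16, alone 1 higher, median 0.11, adjusted p = 0.112, Hspa5 0.43) were not called. Glycolysis passed without the filter (adjusted p = 0.0268) and without 8% replicate 3 (adjusted p = 0.0478), and endoplasmic reticulum folding with quantile normalization (adjusted p = 0.0497) and with only the compared groups in the fit (adjusted p = 0.0313). Among cell type markers luminal (0 of 11, median -0.12, adjusted p = 0.180) and adipocyte genes (0 of 15, median 0.01, adjusted p = 0.879) were not called. Luminal genes passed without 8% replicate 2 (median -0.27, adjusted p = 0.0339).

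**Figure D2:**
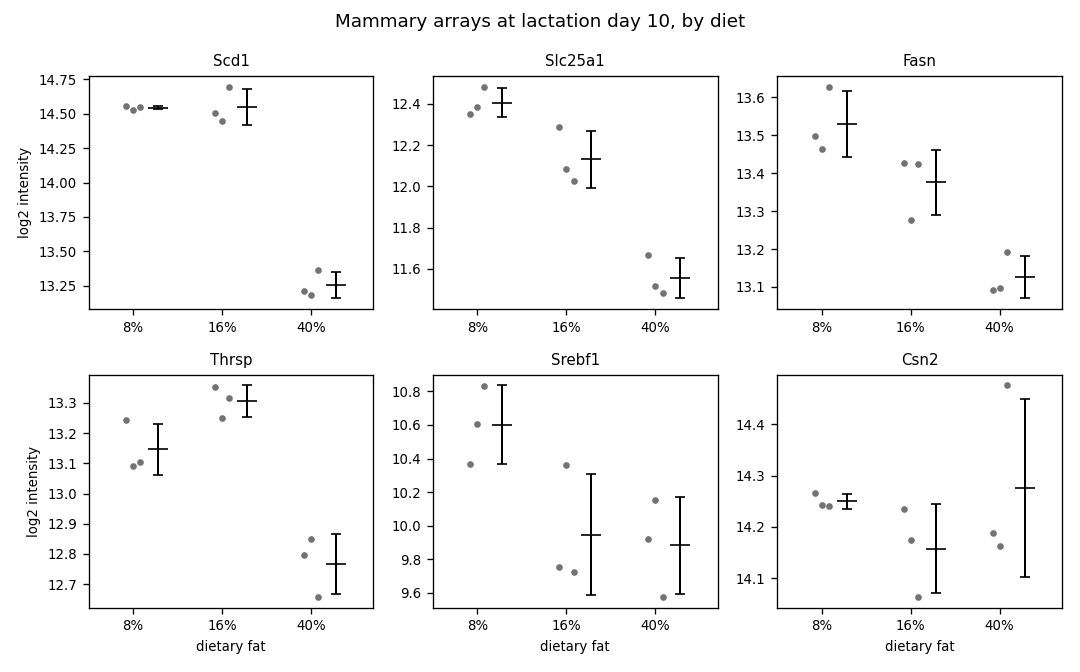
Log2 intensity (vertical axis) of 6 genes in the 9 mammary arrays at lactation day 10 by dietary fat (horizontal axis), where points are arrays, and the dash with its bar is the mean ± SD of 3 arrays. Scd1 was 14.54, 14.55 and 13.26 and Fasn 13.53, 13.38 and 13.13 on 8%, 16% and 40% fat.

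The 16% group, whose feeding is not described, was set against both others. The comparison of 40% against 16% shares its 40% arrays with the comparison above. Against 16%, Scd1 fell by 1.29 (adjusted p = 0.00115) and by 0.81 on its second probe set, and AU020206 (1.08), Procr (1.06), Agt (1.04) and Twf2 (0.86) rose. Crhr1 rose to 5.94 ± 0.20 from 3.32 ± 0.50, which lay below the filter line, so the size of its change was not measured. Crhr1 was lost without 5 of the 6 arrays (adjusted p up to 0.166), and AU020206 and Procr without 40% replicate 1 or 16% replicate 3 (adjusted p up to 0.0792). Thrsp was at -0.54 (adjusted p = 0.0594) and Fasn at -0.25. Limma with Benjamini-Hochberg adjustment called 5 higher and 3 lower of 6483, where 886 passed unadjusted and 1110 did not overlap (17.1%, chance 10%). The total was 1 without 40% replicate 1 or 16% replicate 3, 16 without 40% replicate 3 and 18 without 16% replicate 2. For 16% against 8% it called 0, where 800 passed unadjusted, the lowest adjusted p was 0.174 and 1387 did not overlap (21.4%, chance 10%). Without 8% replicate 2 it called 2 and without 16% replicate 2 it called 1. Scd1 (0.00), Fasn (-0.15) and Srebf1 (-0.66) did not pass there.

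Between 40% and 16% fat camera called fatty acid synthesis, 1 lower of 13, alone 8 (median -0.50, adjusted p = 4.19e-07, adjusted p = 0.0245 with an estimated correlation). Fibroblast and matrix genes had 0 of 15, alone 3 higher (median 0.17, adjusted p = 0.00354, adjusted p = 0.424 with an estimated correlation). Their call was lost without 40% replicate 3 (adjusted p = 0.0511). The pentose phosphate pathway had 0 of 5, alone 3 lower (median -0.41, adjusted p = 0.0226, adjusted p = 0.4503 with an estimated correlation). This was lost without 40% replicate 3 (adjusted p = 0.0781) or 16% replicates 1 (adjusted p = 0.125) or 2 (adjusted p = 0.0666). Glycolysis had 0 of 16, alone 5 lower (median -0.15, -0.24 without 16% replicate 3, adjusted p = 0.0229, adjusted p = 0.4503 with an estimated correlation). The glycolysis call was lost without 40% replicate 3 (adjusted p = 0.0511) or 16% replicates 1 (adjusted p = 0.191) or 2 (adjusted p = 0.0532) and with quantile normalization (adjusted p = 0.0746). Cholesterol synthesis had 0 of 16, alone 3 lower (median -0.27, adjusted p = 0.0342, adjusted p = 0.574 with an estimated correlation). The cholesterol call was lost without 40% replicates 1 (adjusted p = 0.0923), 2 (adjusted p = 0.0932) or 3 (adjusted p = 0.0511) or 16% replicate 2 (median -0.16, adjusted p = 0.175) and with the 75th percentile filter (adjusted p = 0.114). Between 16% and 8% camera called 0 lists. Fatty acid synthesis had a median of -0.09 (adjusted p = 0.316, adjusted p = 0.00643 without the filter), with 0 of 13 called, alone 0.

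Whether genes that rose at the onset of lactation fell on 40% fat was tested over the 4967 genes in both comparisons. Of these 1188 were higher at lactation day 2 and 2 lower on 40% fat, Scd1 and Slc25a1. Both genes were in the overlap, where chance gives 0.478 (Fisher p = 0.0572). With these counts full overlap gives the lowest p the test can reach, so it could not pass. Full overlap of the 2 genes passed without any single lactation day 2 array and without pregnancy day 17 replicates 1, 2 or 4 (Fisher p = 0.0412 to 0.0490), where fewer genes, 1008 to 1100, were higher at lactation day 2. With the 75th percentile filter all 3 genes lower on 40% fat were in the overlap (Fisher p = 0.00737). Full overlap did not pass for the 3 genes with ribosomal medians set equal (Fisher p = 0.291) or for the 2 genes without the filter (Fisher p = 0.172). The overlap was 1 without 40% replicates 2 or 3 and without any single 8% array.

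Liver was compared with mammary gland on 8% fat, 3 arrays each, to set the lipid genes of both organs side by side. By the design text both organs can stem from the same animals, while the fit treated the arrays as independent. Liver held plasma protein genes: Apoa1 at 14.63 ± 0.08 against 2.57 ± 0.03, Alb, albumin, at 14.88 ± 0.24 against 3.42 ± 0.05, Serpina1b (11.82 higher), Serpina1c (11.19), Plg (11.07) and Apoh (10.62). Milk genes were far lower in liver: Csn1s1 at 1.93 ± 0.06 against 15.09 ± 0.04, Wap (-12.41), Glycam1 (-12.32), Csn3 (-12.01), Csn1s2a (-11.98), Csn2 (-11.75) and Lalba (-11.57). In the other organ all these genes lay below the filter line of 4.22, so neither the exact sizes nor the order of these differences were measured. Fasn stood at 11.82 ± 0.03 in liver and 13.53 ± 0.09 in mammary gland. Of 6897 probe sets 2739 were higher and 2779 lower in liver by limma with Benjamini-Hochberg adjustment, 1631 and 1085 by at least 2-fold. The 3 arrays of each group did not overlap for 5731 (83.1%, chance 10%). Setting ribosomal medians equal shifted every change upward by 0.801 and gave 4828 higher and 863 lower. Quantile normalization gave 2248 and 3237 and moved the median of the tested probe sets, which were filtered anew, by -0.21.

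Lipid pathways differed in direction between the organs. In fatty acid synthesis 10 of 13 genes were lower and 2 higher in liver, alone 10 and 2 (median -1.71, camera adjusted p = 0.0118, adjusted p = 0.190 with an estimated correlation, adjusted p = 0.0503 without the filter): Scd2 by -5.91, Slc25a1 by -2.41, Me1 by -1.81, Acly by -1.77, Thrsp by -1.18 and Scd1 by -0.22 (adjusted p = 0.0459, lost without 5 of the 6 arrays, adjusted p up to 0.110, and 0.58 higher with ribosomal medians set equal), with Elovl6, an elongase, 2.19 higher and Dbi 1.59 higher. Beta oxidation gave 22 higher and 1 lower of 23, alone 22 and 1 (median 2.34, adjusted p = 4.12e-06, adjusted p = 0.190 with an estimated correlation). Acaa2 was at 4.71, Cpt1a at 4.64 (8.68 ± 0.08 against 4.04 ± 0.04, below the filter line), Acadl at 3.71 and Slc25a20 at 3.70. Cholesterol synthesis gave 12 higher and 1 lower of 16, alone 12 and 1 (median 1.37, adjusted p = 0.0118, adjusted p = 0.410 with an estimated correlation). Dhcr7 was at 2.95, Sc5d at 2.91, Hmgcs1 at 2.63 and Msmo1 at 2.36, and Sqle at -0.27, not passed. Srebf1 stood at 10.27 ± 0.10 against 10.60 ± 0.23 (adjusted p = 0.0531, adjusted p = 0.0162 without mammary replicate 1), Ppara, a regulator of fatty acid breakdown, was 5.13 higher and Nr1h3 4.06 higher, and Akt1 was at -2.66. Lipid regulators gave 3 higher and 4 lower of 12, alone 3 and 4, with a median of -0.11, a mean of 0.30 and the test downward (adjusted p = 0.620). Triglyceride synthesis gave 5 higher and 5 lower of 12, alone 5 and 5 (median 0.14, adjusted p = 0.751), and uptake 3 higher and 8 lower of 12, alone 3 and 8 (median -1.26, adjusted p = 0.135, adjusted p = 0.00394 with ribosomal medians set equal). Slc27a2 was at 6.82, Lrp1 at 4.56 and Lpl at -7.40. Cpt1a, Ppara and Slc27a2 lay below the filter line in mammary gland, so their exact differences were not measured.

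Carbohydrate and secretory genes split between the organs. Tat (8.91), Fbp1 (8.25), Pck1 (5.80) and Slc37a4 (5.31), of glucose and amino acid handling, were higher in liver. Gluconeogenesis gave 4 higher and 1 lower of 5, alone 4 and 1 (median 5.80, camera adjusted p = 0.0424, adjusted p = 0.190 with an estimated correlation). It was lost without liver replicates 1 (adjusted p = 0.0576) or 3 (adjusted p = 0.0617) and with ribosomal medians set equal (adjusted p = 0.107) or the 75th percentile filter (adjusted p = 0.154). Aldoc (-5.48), Pkm (-4.55), Slc2a1 (-4.30) and Hk2 (-3.76) were lower. Glycolysis gave 3 higher and 11 lower of 16, alone 3 and 11 (median -0.84, adjusted p = 0.0118, adjusted p = 0.190 with an estimated correlation, adjusted p = 0.0668 without the filter). All 13 milk protein genes were lower, alone 13 (median -11.57, adjusted p = 4.31e-10, adjusted p = 0.0943 with an estimated correlation), and all 10 milk fat globule genes, alone 10 (median -6.55, adjusted p = 2.35e-06, adjusted p = 0.190 with an estimated correlation). Cidea was at -11.25, Btn1a1 at -11.16, Fabp3 at -10.08 and Muc1 at -9.49. The exact differences of Tat and Fbp1, below the filter line in mammary gland, and of Slc2a1, Cidea, Btn1a1 and Muc1, below it in liver, were not measured. Ribosomal proteins gave 2 higher and 10 lower of 12, alone 2 and 10, with a median of -0.76 that turned to 0.04 when ribosomal medians were set equal (adjusted p = 0.0303, adjusted p = 0.355 with an estimated correlation, adjusted p = 0.0600 with quantile normalization). The ribosomal scaling fixes this list by construction, so the turn does not test its difference. Pentose phosphate (2 higher, 3 lower of 6, median -0.60, mean 0.14, test downward, adjusted p = 0.541), lactose (3, 5 of 8, adjusted p = 0.272, but adjusted p = 0.0235 with ribosomal medians set equal), pyruvate and citric acid cycle (13, 7 of 22, adjusted p = 0.332), amino acid transport (3, 5 of 8, adjusted p = 0.400), endoplasmic reticulum (10, 6 of 17, alone 10, 7, adjusted p = 0.400) and cell cycle genes (2, 6 of 12, adjusted p = 0.144) were not called. Apart from the endoplasmic reticulum list the counts alone were unchanged.

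Cell type markers separated the organs. All 20 hepatocyte genes were higher in liver, alone 20 (median 9.31, camera adjusted p = 5.04e-11, adjusted p = 0.0413 with an estimated correlation). Interferon and inflammation gave 10 higher and 2 lower of 13, alone 10 and 2 (median 1.37, adjusted p = 0.0424, adjusted p = 0.190 with an estimated correlation). The acute-phase gene Hp was at 7.79 and Orm1 at 12.76 against 6.75. The call was lost without liver replicates 1 (adjusted p = 0.05001) or 3 (adjusted p = 0.0565), with ribosomal medians set equal (adjusted p = 0.147) and with the 75th percentile filter (adjusted p = 0.154). Lower in liver were myoepithelial genes, 6 of 6, alone 6 (median -3.90, adjusted p = 0.00232, adjusted p = 0.190 with an estimated correlation, Acta2 -6.35), luminal genes, 8 lower and 3 higher of 11, alone 8 and 3 (median -2.23, adjusted p = 0.0152, adjusted p = 0.190 with an estimated correlation, Elf5 -8.44, Epcam -5.08), brown adipocyte genes, 5 of 5, alone 5 (median -0.91, adjusted p = 0.0126, adjusted p = 0.190 with an estimated correlation), and adipocyte genes, 11 lower and 3 higher of 15, alone 11 and 3 (median -1.11, adjusted p = 0.0245, adjusted p = 0.422 with an estimated correlation, Adipoq -6.46). Fibroblast and matrix genes gave 11 lower and 1 higher of 15, alone 12 and 1 (median -1.21, adjusted p = 0.0137, adjusted p = 0.445 with an estimated correlation), and lymphocyte genes 8 lower of 8, alone 8, with a median of -0.61 that turned to 0.22 when ribosomal medians were set equal (adjusted p = 0.0137, adjusted p = 0.190 with an estimated correlation, adjusted p = 0.0501 under that scaling, Ighm -8.87). Macrophage genes gave 7 higher and 1 lower of 10, alone 7 and 1 (median 1.64, adjusted p = 0.0771, Lyz2 2.64), and endothelial genes 4 higher and 5 lower of 9, alone 4 and 5 (adjusted p = 0.541). Flt1 was at -1.03 with another probe set 0.92 higher. Without the filter the luminal (adjusted p = 0.0503), fibroblast (adjusted p = 0.0695), adipocyte (adjusted p = 0.0996) and ribosomal protein (adjusted p = 0.0574) calls were lost. The 75th percentile filter ended the luminal (adjusted p = 0.0723), fibroblast (adjusted p = 0.0723) and adipocyte (adjusted p = 0.157) calls and left too few brown adipocyte and lymphocyte genes for a test, and quantile normalization ended the adipocyte and lymphocyte calls (adjusted p = 0.0600 each). Acta2, Elf5, Epcam, Adipoq and Ighm lay below the filter line in liver, so their exact differences were not measured.

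**Figure D3:**
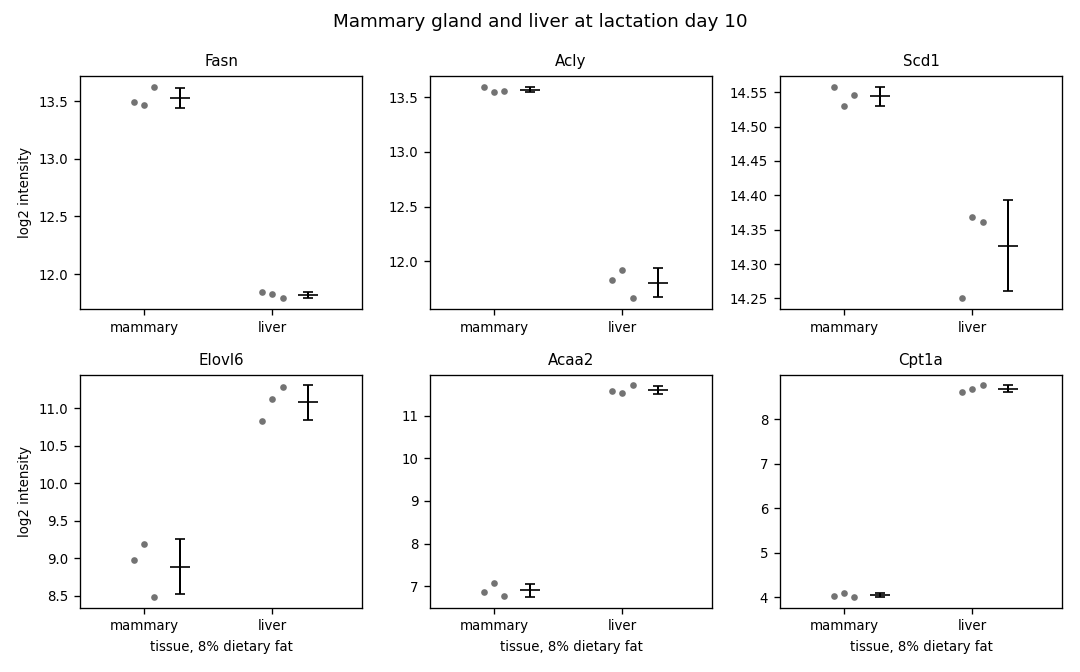
Log2 intensity (vertical axis) of 6 lipid genes in mammary gland and liver on 8% fat (horizontal axis), where points are arrays, and the dash with its bar is the mean ± SD of 3 arrays. Fasn was 13.53 in mammary gland and 11.82 in liver, and Cpt1a 4.04 (below the filter line) and 8.68.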

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

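Whether an array lay apart from the other 3 of its stage was tested by a rule fixed before the data were examined, with no test chosen after the result was seen. Of 190 groups of 4 values tested, 9 had an array whose gap to the nearest other, over the range, passed Dixon's 95% limit, and chance gives about 1 in 20. The cholesterol synthesis mean of pregnancy day 12 replicate 2 was 6.139, against 5.753 to 5.809 in the others. The gluconeogenesis and ketogenesis mean of pregnancy day 12 replicate 4 was 5.434, against 5.736 to 5.778. The triglyceride synthesis mean of pregnancy day 17 replicate 2 was 6.55, against 6.619 to 6.627. Lactation day 1 replicate 1 had a beta oxidation mean of 6.557 against 6.695 to 6.702, a lactose synthesis mean of 7.833 against 8.04 to 8.053, and Wap at 15.76 against 15.55 to 15.59. The myoepithelial mean of lactation day 1 replicate 4 was 6.274, against 6.18 to 6.184. The lymphocyte mean of lactation day 2 replicate 3 was 4.591, against 4.17 to 4.231. The lymphocyte mean of lactation day 9 replicate 2 was 4.391, against 4.662 to 4.688.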

How the results depend on the processing

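All alternatives here were chosen before the results were seen, except leaving lactation day 9 replicate 1 out of the other stage comparisons. Where a value moved without a construction that fixes it, the cause was not tested.

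The filter sets how many probe sets enter. Without it, lactation day 2 against pregnancy day 17 gave 7676 calls (5819 higher, 1857 lower) in place of 3589, pregnancy day 17 against 12 gave 6873 (4624 and 2249) in place of 3245, liver against mammary gland 10292 (2947 and 7345) in place of 5518, any change 11102 in place of 6293, and 40% against 16% fat 5 in place of 8. With the 75th percentile these were 2107 (704 and 1403), 1890 (671 and 1219), 3368 (1987 and 1381), 3538 and 22. Liver lists called, 16 in the reported analysis, were 10 without the filter and 9 with the 75th percentile. The stage and diet overlap was 3 genes with the 75th percentile (Fisher exact p = 0.00737) and with ribosomal medians set equal (p = 0.291), and 2 without the filter (p = 0.172).

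Setting ribosomal protein medians equal shifts every array by that list, so it turned calls upward where ribosomal genes were low. It gave 5664 calls (5086 higher, 578 lower) for lactation day 2 against pregnancy day 17, 4681 (4268 and 413) for lactation day 1 against pregnancy day 17, 2849 (2497 and 352) for lactation day 2 against day 1, 3848 (2219 and 1629) for pregnancy day 17 against 12, a split of 4828 and 863 for liver, and 18 for 40% against 16% fat. It adds the same shift to every gene, given in the Results, so every smaller fall turned upward. At lactation day 2 against pregnancy day 17 these included Sparc (0.49), Col1a1 (0.02), Plin2 (0.13), Slc2a4 (0.41), Fabp3 (0.51), Lmf1 (0.0372), Fabp4 (0.11), Echs1 (0.43), Taldo1 (0.13), Sdhb (0.52), Rps3 (0.0041), Rps4x (0.36), Irf1 (0.44), Trp63 (0.0215) and Mpeg1 (0.44). In liver they included Scd1 (0.58), Sqle (0.53), Mvd (0.55), Srebf1 (0.47), Pfkm (0.73), Ddit3 (0.56), Pcna (0.79), Dcn (0.64), Sparc (0.51), Cd3d (0.17), Myl1 (0.28) and Tnnt3 (0.42).

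Among genes that passed in either setting, quantile normalization turned Gnpat (-0.35), Lmf1 (-0.30), Mbtps1 (-0.27), Pgk1 (-0.44), Mdh2 (-0.50) and C1qa (-0.53) in liver. It gave 16 calls for 40% against 16% fat and splits of 1553 and 1460 for pregnancy day 17 against 12, 937 and 925 for lactation day 9 against 2, and 2248 and 3237 for liver.

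Asking for at least 2-fold left 744 (240 and 504), 767, 397, 106 and 445 calls in the stage comparisons in the order of the report, 1 for 40% against 8% fat, 5 for 40% against 16%, 2716 for liver and 0 overlap genes. With only the compared groups in the fit, 40% against 8% gave 1, 40% against 16% gave 13 and the overlap 1. Trended and robust variances gave 28 and an offset of 16 gave 18 for 40% against 16%. With an estimated correlation, 0 lists were called at lactation day 2 against pregnancy day 17, 1 for 40% against 8% (fatty acid synthesis) and 1 for liver (hepatocyte markers). The fatty acid synthesis median for 40% against 8% ran from -0.39 to -0.51 over single arrays left out.

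Leaving out arrays in turn gave 3113 to 3571 calls for lactation day 2 against pregnancy day 17, 2764 to 3275 for pregnancy day 17 against 12, 1340 to 1739 for lactation day 1 against pregnancy day 17, 523 to 1332 for lactation day 2 against 1, 1470 to 2104 for lactation day 9 against 2, 1 to 4 for 40% against 8%, 1 to 18 for 40% against 16%, 0 to 2 for 16% against 8%, 5226 to 5398 for liver, 6111 to 6357 for any change and 1 to 2 for the overlap. The highest of the first 3 ranges, 3571, 3275 and 1739, came from leaving lactation day 9 replicate 1 out of the shared spread, which gave 1059 for lactation day 2 against 1. Lists called ran from 13 to 15 at lactation day 2 against pregnancy day 17, 3 to 6 for 40% against 8% and 14 to 16 for liver.

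The groups share replicate numbers only in their titles, and liver and mammary arrays on 8% fat can stem from the same dams, which the reported fit left out. Deviations of arrays with the same number correlated at -0.230 to 0.268 in the time course, -0.180 to 0.142 in the diets and -0.00770 to 0.0216 between tissues. Of the arrays, 6 of 20, 5 of 9 and 1 of 6 correlated best with their own number. Medians with the same and with another number were 0.0054 and 0.0053, 0.0577 and -0.0150, and 0.0106 and -0.0054. No clear pairing was seen, but such weak correlations cannot exclude it, so pairing stays open. With the number as a replicate block, 40% against 8% gave 1 call, 40% against 16% gave 5, the overlap 1, lactation day 2 against pregnancy day 17 gave 3595 and liver 5416 (2705 and 2711) in place of 5518; the pyruvate and citric acid cycle list for 40% against 8% (adjusted p = 0.0564) and cholesterol synthesis for 40% against 16% (adjusted p = 0.0543) were lost.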

Other observations

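The tests of the 3 patterns and those by regrouping the arrays, with their limits, were chosen after the results were seen, apart from the one of RNA degradation.

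Over the 5 stages the mean of the milk protein list was 11.21, 12.98, 13.73, 14.03 and 14.02, and that of cholesterol synthesis 5.87, 5.92, 6.90, 6.92 and 6.35. Cell cycle genes had 2 high points, 6.22 at pregnancy day 12 and 6.09 at lactation day 2, with 4.83 at pregnancy day 17, 5.47 at lactation day 1 and 4.51 at lactation day 9.

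Probe sets of low intensity were higher at lactation day 2 than at pregnancy day 17. Of 5233 probe sets below the filter line 94.3% were higher, with a median change of 0.194, while 3067 bright ones had a median of -0.135, and the hepatocyte and muscle markers, 22 dim genes, had 0.241. The mean 25th percentile of the arrays rose from 7.49 at pregnancy day 12 through 8.21, 8.61 and 9.38 to 10.1 at lactation day 9, so a background or scaling difference in the deposited values may account for these small rises. Liver cells in the samples are excluded, since the 5 hepatocyte markers brightest in liver stood at 3.54 ± 0.06 at lactation day 2 against 14.6 in liver. Whether dim genes were transcribed more was not tested.

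Lactation day 9 replicate 1 was the lowest of its stage in fibroblast and erythrocyte list means, though its gap over the range (0.749 and 0.754) did not pass Dixon's limit. A mislabelled diet array is excluded, since its distance to the other lactation day 9 arrays (0.356) was below that to the nearest diet group (0.453). More RNA degradation than in the other mammary arrays was not seen. The actin 3' to 5' difference of this array, 1.52, lay within their 1.18 to 1.88. Its Gapdh difference of 0.05 lay within their -0.19 to 0.90. The other arrays may be degraded as well, so degradation itself is not excluded. Less stroma and blood in the sampled tissue might be the cause: 3 of 4 list means lay below the other arrays by more than their SD (fibroblast 5.82 against 6.77 to 7.08, erythrocyte 4.81 against 6.14 to 6.57, macrophage 5.16 against 5.33 to 5.39; endothelial 5.84 against 5.87 to 6.06). The test left this open.

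Fatty acid synthesis genes were lower on 40% than on 8% fat. Fewer epithelial cells as the whole cause of the median of -0.44 are excluded, since the milk fat globule genes, at 14.5 or lower where the scale reached 15.8, had a median of -0.00590 with an SD of 0.143 over genes. The milk protein median of -0.0211 adds little so near the top of the scale, and a smaller loss stays open, with 9 of 11 luminal genes below 0 (median -0.124, -0.27 without 8% replicate 2, where the list passed) and the myoepithelial median at -0.21 (adjusted p = 0.0328, but 0.597 with an estimated correlation, and lost without 4 of the 6 arrays and with the 75th percentile filter). A single atypical array is excluded, since leaving out any array gave a median of -0.393 or further from 0 and an adjusted p of at most 3.91e-12. Dietary fat content is consistent with the median of -0.497 for 40% against 16% and -0.0897 for 16% against 8%; the former uses the same 3 arrays on 40% fat, so it is not independent, and whether those arrays were processed apart was not tested.

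For each stage comparison the arrays were regrouped in all 35 possible splits. Of 35 splits only 1, the real grouping, gave as many calls each time: 3589 with 4 in the highest other split, 3245 with 111, 1674 with 210, 1027 with 25 and 1797 with 20. This speaks against chance without excluding it, since 1 of 35 is the lowest share these splits can give. For any change, with stage labels shuffled at random, the real grouping was 1 of 100 (6293). The highest other gave 2964, for a cause that was not tested. For 40% against 8% fat (6 calls; highest other 1; 1 of 10 splits), 40% against 16% (8; 1; 1 of 10), 16% against 8% (0; 0; 10 of 10) and liver (5518; 0; 1 of 10) the 10 splits are too few to show a share under 0.05.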
